A study of Homo sapiens with 12 samples.

How the data were processed

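Total RNA of 12 MCF10A samples, 3 each of control, MYC, AURKB and HRAS cells, was poly-A selected and made into paired-end Illumina libraries with a NEB kit, per the labels. The strand setting of the library kit and of the counting is not given in the sources used here. The submitters' processing notes name CASAVA, STAR 2.5, HTSeq 0.6.1 and DESeq2 and the build GRCh37/hg19, without stating the order or role of each. The read counts per gene were made by the authors from aligned reads and were deposited without normalization. The log2 fold changes of each oncogene group over control were computed by the authors, with each comparison normalized separately. The adjusted p-values per comparison were likewise deposited by the authors. The gene length, start and end were given by the authors, per the file headers. The FPKM columns were not used, since counts of the same samples were present.

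The table held 48162 genes in 12 libraries of 19638917 to 24979082 counts. Genes passing filterByExpr (15004) were scaled by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with 1 mean per group and 8 residual degrees of freedom. Genes were called at an adjusted p under 0.05 (Benjamini-Hochberg). The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. Except where stated, these choices, the alternatives and the gene lists were set before the data were examined. Genes at 0 counts in 1 group were given a lower bound on the fold with a floor of 3 counts over the group, and those with 1 to 3 counts the ratio with a 95% counting interval, which covers counting error only.

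Of 31 gene lists, 30 were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and the 3 comparisons with control. The lists covered ribosome biogenesis, nucleotide synthesis, glycolysis, oxidative phosphorylation, cholesterol, fatty acid and ceramide metabolism, ESCRT machinery, vesicle docking, tetraspanins, lysosome, autophagy, ERK output, mesenchymal, epithelial junction, keratinization, basal, luminal, inflammatory, interferon, mitosis, DNA replication, p53, ATF4, ER chaperone and NRF2 genes, 3 other cell types and 2 marks of RNA quality. Camera tests a list against the other genes. The estimated correlation was an alternative within camera, and fry, which tests a list against no change, was another. The same lists between 2 oncogene lines, the tests on genes with no opposite-strand gene, and the PPARG list were added after the data were seen.

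Genes are named by a fixed rule: the introduced oncogenes, the 5 largest called rises and falls of protein-coding genes at 10 CPM or more with no overlap between the libraries of the 2 groups (3 between oncogene lines), the 2 largest called changes of each metabolic and vesicle list and of ERK output at 5 CPM or more, the 2 largest of every other called list, the 5 largest shared by all 3 lines, and 9 vesicle genes chosen in advance. The rule was applied again to genes with no opposite-strand gene after the data were seen. Opposite-strand genes were found from the gene spans in the authors' table. The share of exonic bases overlapped and GC content came from GENCODE 29, which matched 45342 gene IDs (14580 of the tested ones) and served only for gene properties.

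Alternatives were DESeq2 1.42.0, limma-voom, edgeR with a minimum fold (glmTreat), other scalings, a stricter filter and no filter, replicate number as a block, fits of only the 2 groups compared, and each library left out in turn. In a self-test on simulated counts of 15004 genes, 2-fold changes were recovered in 58.2%, 67.2% and 71.6% of changed genes in the MYC, AURKB and HRAS comparisons, and 10, 4 and 3 unchanged genes were called. A lysosome list raised 1.3-fold was recovered, with 0 of 89 other tests called. Genes were drawn independently in this self-test, so it cannot show how camera behaves on lists of correlated genes. At each fold only 66 or 67 genes were changed, far fewer than were called in the data.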

Results

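Poly-A RNA was sequenced from 12 libraries of MCF10A, an immortalised and non-tumorigenic human mammary epithelial cell line. Cells expressing MYC (a transcription factor), AURKB (a mitotic kinase) or HRAS (a signalling GTPase) were set against a Puro/Blast control line, with 3 libraries per group. The series asks which metabolic pathways change with each oncogene and bear on the release of extracellular vesicles. The libraries held 19638917 to 24979082 counts over annotated genes, and 15004 of the 48162 genes in the table had enough counts for a test. Levels are counts scaled to library size (CPM, mean ± SD, n = 3), and log2 fold changes carry the standard error of the edgeR fit. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera. The first component of the expression values held 55.6% of the variance and set HRAS libraries apart, and the second held 26.4% and set AURKB libraries apart from control libraries. On the first component AURKB libraries (17.6 to 18.4) also lay above MYC and control libraries (-81.2 to -58.9). This is the same split as in the opposite-strand counts below, and no components were computed for genes with no opposite-strand gene.

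**Figure D1:**
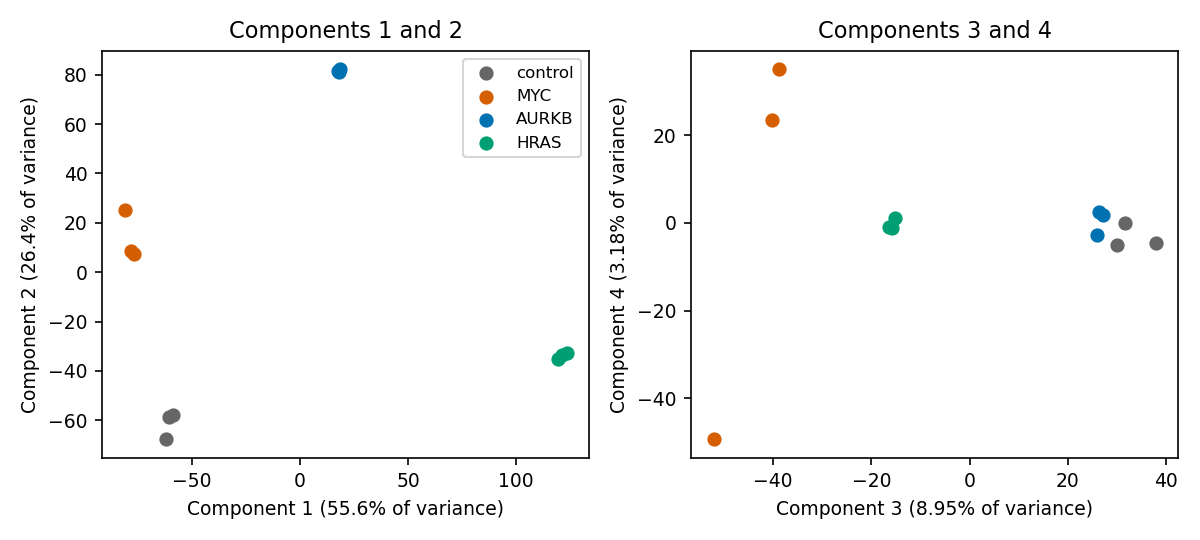
Principal component scores (arbitrary units) of the 12 libraries on log2 CPM of the tested genes, 1 point per library. Components 1 and 2 hold 55.6% and 26.4% of the variance, and component 4 (3.18%) parts MYC replicate 1 at -49.3 from MYC replicates 2 and 3 at 23.4 and 35.0.

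One MYC library stood apart from its group. Between MYC replicates 2 and 3 the counts differed with a chi-square of 4.28 per degree of freedom, against 61.5 and 69.1 between replicate 1 and each of them. In MYC replicate 1, 558 genes were 2-fold or more above the mean of the other 2 MYC libraries and 1060 were 2-fold or more below, while single libraries of the other groups had 246 to 583 such genes in both directions together.

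Counts over genes that share their position with a gene on the opposite strand followed the same split of the libraries throughout. Of the 15004 tested genes, 7125 overlapped no opposite-strand gene in the authors' table. In the 45 genes with over 95% of their exonic bases overlapped, the median log2 fold change was 8.49 in AURKB and 8.96 in HRAS cells against control, 0.00 in MYC cells, and -0.52 between AURKB and HRAS cells. In MYC cells both quartiles were 0.00 too, as genes with no count in either group give, so this median does not show an unchanged level. The 8.49 and 8.96 are fitted values and not lower bounds. In the 7338 genes with no exonic overlap the same medians were -0.05, -0.04, 0.03 and 0.03. These medians cover only tested genes that reached a minimum mean CPM over all groups. Genes with no count in control and MYC cells could reach it only through the AURKB and HRAS libraries. No group had libraries on both sides of this split, so no value within a side could be had for AURKB or HRAS cells against control, and gene numbers below are also given for the 7125 genes alone. These genes may still carry any other difference between the libraries of each side. Such a difference cannot be told apart from the effect of the oncogenes.

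**Figure D2:**
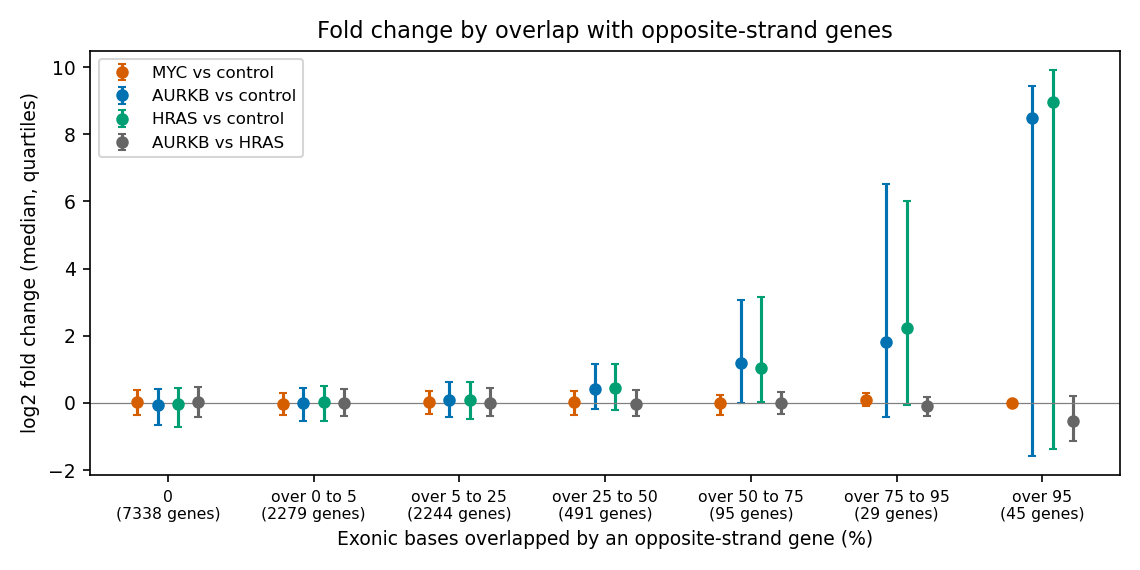
Median log2 fold change (points) with quartiles (bars) of tested genes that reached a minimum mean CPM over all groups, in bins of the share of exonic bases that an opposite-strand gene overlaps (%), for 4 comparisons. AURKB and HRAS cells against control climb to medians of 8.49 and 8.96 in the last bin, while MYC against control and AURKB against HRAS lie at 0.00 and -0.52. In that bin the quartiles of MYC against control are 0.00 too, as genes with no count in either group give.

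The introduced oncogenes were high in the cells named after them. MYC (ENSG00000136997, chromosome 8, 128747680 to 128753674; all positions on GRCh37) rose from 242 ± 23.4 to 988 ± 44.7 CPM, a log2 fold change of 2.03 ± 0.08 (adjusted p = 2.86e-09). AURKB (ENSG00000178999, chromosome 17, 8108056 to 8113918) rose from 29.5 ± 2.32 to 3339.5 ± 75.3 CPM in AURKB cells (6.82 ± 0.10, adjusted p = 1.18e-13). It rose to 66.7 ± 5.15 CPM in MYC cells (1.18 ± 0.08) and fell to 18.2 ± 1.53 CPM in HRAS cells (-0.69 ± 0.09). HRAS (ENSG00000174775, chromosome 11, 532242 to 537287) rose from 60.5 ± 1.03 to 721 ± 48.8 CPM in HRAS cells (3.57 ± 0.17, adjusted p = 9.99e-10) and fell to 39.2 ± 2.199 CPM in AURKB cells (-0.63 ± 0.16). MYC levels of 267 ± 13.6 CPM in AURKB cells and 220.0 ± 5.06 CPM in HRAS cells did not pass the test against control (adjusted p = 0.109 and 0.1202), nor did the HRAS level in MYC cells (-0.24 ± 0.16, adjusted p = 0.219). These 3 depended on single libraries. MYC passed in AURKB cells without control replicate 2 (0.22 ± 0.07, adjusted p = 0.0187) and in HRAS cells without control replicate 3 (-0.20 ± 0.08, adjusted p = 0.0373), and HRAS passed in MYC cells without MYC replicate 1 (-0.54 ± 0.08, adjusted p = 1.74e-05). With each library left out in turn their adjusted p ran from 0.0187 to 0.366, from 0.0373 to 0.491 and from 1.74e-05 to 0.643. Counts of an introduced transcript cannot be told from those of the resident gene.

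**Figure D3:**
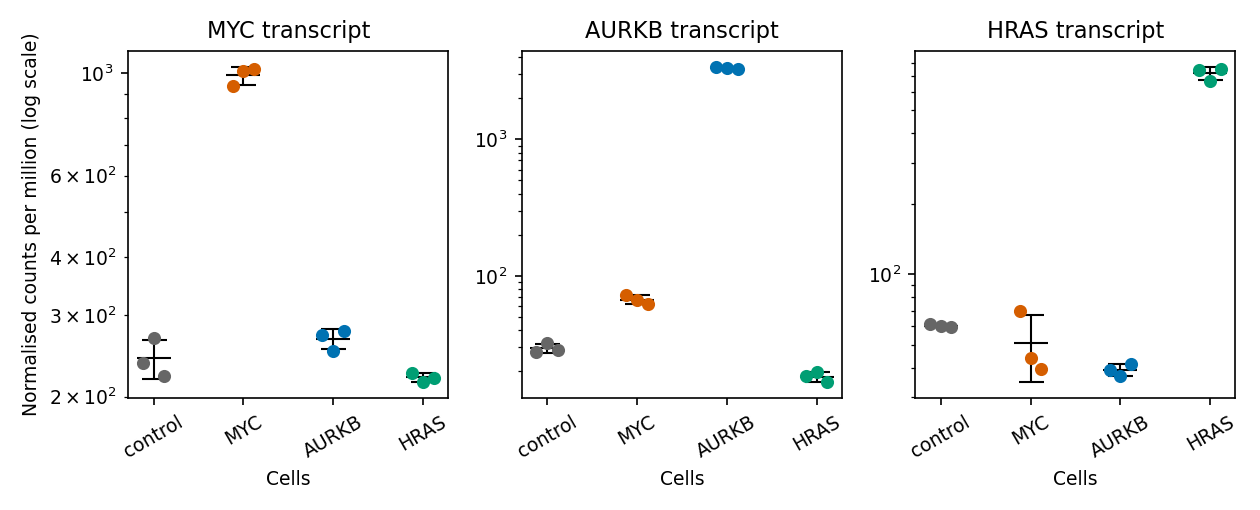
Normalised CPM (log axis) of MYC, AURKB and HRAS in each library, grouped by cells, with the mean and SD as bars (n = 3). Each oncogene was highest in its own cells, at 988, 3339.5 and 721 CPM against 242, 29.5 and 60.5 CPM in control cells.

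In MYC cells, genes of cell division and ribosome assembly rose while genes of the lysosome, the vesicle membrane and the interferon response fell. Of the mitosis genes 30 of 35 tested members rose and 0 fell (31 and 0 adjusted over the list alone), with a camera adjusted p of 3.67e-10 and an adjusted p of 0.366 with an estimated correlation, 1.88e-11 to 0.366 over the camera settings. UBE2C, which marks mitotic proteins for destruction, rose from 41.99 ± 6.04 to 114 ± 10.3 CPM, and INCENP, a partner of the AURKB kinase, rose by 1.14 ± 0.09 on the log2 scale. Among DNA replication genes 26 rose and 0 fell of 37 (28 and 0 adjusted over the list alone), with an adjusted p of 5.19e-06 (0.656 with an estimated correlation, 1.58e-08 to 0.656 over the camera settings). Cyclin E1 (CCNE1) rose from 4.48 ± 0.164 to 15.3 ± 8.33 CPM and the transcription factor E2F1 from 11.9 ± 1.16 to 31.7 ± 9.83 CPM. In the ribosome biogenesis list 27 of 35 tested members rose and 0 fell (29 and 0 adjusted over the list alone), at an adjusted p of 1.40e-06 (0.544 with an estimated correlation, 3.09e-08 to 0.544 over the camera settings). The largest rises there were those of the pseudouridine synthase PUS7 (1.28 ± 0.17) and the nucleolar protein NOP56 (1.13 ± 0.21). Nucleotide, one-carbon and polyamine synthesis genes rose in 17 of 30 cases and fell in 2 (18 and 2 adjusted over the list alone), with an adjusted p of 5.75e-04 (0.544 with an estimated correlation, 1.59e-04 to 0.544 over the camera settings). IMPDH1, of guanine nucleotide synthesis, rose from 122 ± 12.1 to 293 ± 32.1 CPM, and the ribonucleotide reductase subunit RRM2 from 124 ± 4.75 to 289 ± 111 CPM. ER chaperone genes followed, where 11 rose and 1 fell of 20 (12 and 1 adjusted over the list alone), including HYOU1 (1.03 ± 0.06) and HSPA5 (0.99 ± 0.11), at an adjusted p of 0.00154 (0.544 with an estimated correlation, 1.65e-04 to 0.544 over the camera settings).

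Lysosome genes fell in 30 of 49 cases and rose in 4 (31 and 4 adjusted over the list alone), with a camera adjusted p of 9.25e-06 and an adjusted p of 0.290 with an estimated correlation, 4.86e-06 to 0.290 over the camera settings. The acid alpha-glucosidase gene GAA fell from 45.7 ± 7.98 to 9.39 ± 4.38 CPM and the cathepsin gene CTSO from 8.15 ± 0.581 to 1.902 ± 0.202 CPM. Of tetraspanin and vesicle membrane genes 1 of 33 tested members rose and 22 fell (3 and 24 adjusted over the list alone), at an adjusted p of 5.65e-06 (0.290 with an estimated correlation, 1.02e-06 to 0.290 over the camera settings). TSPAN1 fell from 124 ± 19.2 to 13.9 ± 1.04 CPM and LGALS3BP from 215 ± 3.27 to 77.96 ± 25.2 CPM. Interferon response genes fell in 18 of 32 cases and rose in 1 (19 and 1 adjusted over the list alone, adjusted p = 6.20e-04, and 0.490 with an estimated correlation, 1.28e-04 to 0.490 over the camera settings). BST2, a membrane tether of virus particles, fell from 51.3 ± 5.34 to 6.298 ± 3.98 CPM, and RSAD2 was at least 10.8-fold lower than its 0.4902 ± 0.2698 CPM in control cells. In fatty acid synthesis and desaturation 3 rose and 12 fell of 21 (3 and 12 adjusted over the list alone), at an adjusted p of 0.00134 (0.332 with an estimated correlation, 8.32e-04 to 0.606 over the camera settings). The desaturase FADS2 fell by 2.36 ± 0.27 and the acyl-CoA synthetase ACSL4 by 1.74 ± 0.09 on the log2 scale. Replication histone genes, whose main transcripts lack poly-A tails, moved one way, since 0 rose and 7 fell of 8 (0 and 7 adjusted over the list alone, adjusted p = 7.95e-04, and 0.290 with an estimated correlation, 1.94e-04 to 0.290 over the camera settings), among them HIST2H2BE (-3.07 ± 0.20) and HIST1H2AC (-2.66 ± 0.18). Among the 7125 genes with no opposite-strand gene, the nucleotide, fatty acid and interferon lists did not pass (adjusted p = 0.0511, 0.606 and 0.0838). With tested members down from 30 to 18, 21 to 9 and 32 to 19, their median log2 fold changes in the fit of all genes went from 0.32 to 0.31, -0.66 to -0.15 (-0.42 over all members without MYC replicate 1) and -0.78 to -0.70.

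Keratinization genes, markers of the upper layers of stratified epithelium, rose in 16 of 24 cases and fell in 3 (16 and 3 adjusted over the list alone), with an adjusted p of 0.00416 (0.769 with an estimated correlation, 1.51e-05 to 0.769 over the camera settings). This group moved with MYC replicate 1, where its median log2 difference from control was 3.82, against 1.40 and 0.91 in replicates 2 and 3. Without that library 13 rose, 5 fell and the median dropped from 2.56 to 0.93 (adjusted p = 0.0316). The median of ribosome biogenesis genes was 0.63 in that library against 0.30 and 0.24 in replicates 2 and 3, of DNA replication 0.82 against 0.41 and 0.30, of nucleotide synthesis 0.43 against 0.21 and 0.22 and of fatty acid synthesis -0.89 against -0.43 and -0.41. Without it the medians of the DNA replication, nucleotide and fatty acid lists went from 0.53 to 0.35, 0.32 to 0.21 and -0.66 to -0.42, and these lists still passed (adjusted p = 1.59e-04, 0.00153 and 0.00188), as did ribosome biogenesis (0.40 to 0.28, adjusted p = 7.88e-06). The keratin KRT4 had a log2 fold change of 7.72 ± 1.41 over all libraries and 5.60 without MYC replicate 1. For KRT6C these values were 6.22 ± 1.22 and 3.55, and for the ammonium transporter RHCG 6.12 ± 0.72 and 5.42 (194-fold, interval 53.5 to 1607 without control replicate 3). With limma-voom in place of edgeR, KRT4 and KRT6C did not pass. The mesenchymal, p53 and ATF4 lists did not pass over all MYC libraries (adjusted p = 0.235, 0.235 and 0.207) and passed without MYC replicate 1 (adjusted p = 0.0177, 0.0256 and 0.0295), against highest values of 0.723, 0.718 and 0.656 over the camera settings.

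The calcium-binding protein calbindin 1, CALB1 (ENSG00000104327, chromosome 8, 91070836 to 91107703), rose from 1 count over the control libraries to 27.2 ± 7.92 CPM, 1775-fold (95% counting interval 318 to 70128). Guanine deaminase, GDA (ENSG00000119125, chromosome 9, 74729511 to 74872109), reached 29.05 ± 7.39 CPM, 630.4-fold (95% counting interval 215 to 3059.6), and the phosphodiesterase PDE3B 10.1 ± 2.13 CPM, 654-fold (95% counting interval 117 to 25863). All control counts of these 3 genes lay in control replicate 1, without which the rises were at least 399-fold, at least 425-fold and at least 146.9-fold. The adhesion adaptor PARVB rose from 0.562 ± 0.0271 to 55.9 ± 7.53 CPM (6.62 ± 0.17). BGN, a matrix proteoglycan, stood at 38.1 ± 29.5 CPM with a log2 fold change of 7.63 ± 1.02, a call that was lost with limma-voom. NRSN2 fell from 27.5 ± 5.42 to 0.379 ± 0.181 CPM, TDRD5 from 12.3 ± 2.17 to 0.0943 ± 0.0829 CPM and the calpain CAPN6 from 10.2 ± 4.34 to 0.0759 ± 0.021001 CPM. FIBIN fell by 7.04 ± 0.55 on the log2 scale (-6.44 without MYC replicate 1 and 238-fold, interval 65.6 to 1966 without replicate 2), and the receptor TREM1 by 5.81 ± 0.57 (-5.16 without control replicate 3 and -6.60 without MYC replicate 2). Of nuclear-encoded oxidative phosphorylation genes 8 of 40 tested members rose and 6 fell (8 and 6 adjusted over the list alone), at an adjusted p of 0.981, median -0.06, mean 0.04, test upward. Without control replicate 1, 7 rose and 14 fell. Cytochrome c (CYCS) rose from 260.4 ± 12.7 to 544 ± 50.6 CPM and UQCRFS1 by 0.60 ± 0.09 on the log2 scale. Cholesterol synthesis and uptake genes had 4 risen and 11 fallen members of 24 (4 and 11 adjusted over the list alone, adjusted p = 0.114), with TM7SF2 at -1.90 ± 0.19 and PMVK at -1.01 ± 0.07. Without MYC replicate 1, 8 rose and 11 fell (median -0.08, adjusted p = 0.811), and without MYC replicate 3 the list passed (adjusted p = 0.0351, 0.0351 to 0.828 over the camera settings). Glycolysis genes had 3 risen and 8 fallen members of 23 (3 and 8 adjusted over the list alone, adjusted p = 0.148), and neuronal enolase (ENO2) and the lactate exporter SLC16A3 fell by 1.71 ± 0.25 and 1.28 ± 0.07.

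Over all tested genes, 3682 rose and 3520 fell in MYC cells, of which 872 and 1368 changed 2-fold or more. Among the 7125 genes with no opposite-strand gene, 1891 rose and 1647 fell (493 and 662 at 2-fold or more), or 1832 and 1723 (481 and 683) when scaled and fitted alone. In the authors' deposited results, 2758 genes rose and 2667 fell at an adjusted p under 0.05, and the 5302 genes called both there and here all had the same sign.

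In AURKB cells genes of cell division rose, and genes of the interferon response, epithelial junctions and the vesicle membrane fell. Of the mitosis genes 33 of 35 tested members rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 fold change of 1.04, a camera adjusted p of 2.01e-12 and an adjusted p of 0.290 with an estimated correlation, 3.22e-13 to 0.290 over the camera settings. ASPM, a spindle pole protein, rose from 138 ± 23.3 to 394 ± 19.6 CPM. BIRC5 (survivin), a partner of AURKB, rose from 13.98 ± 0.933 to 129.7 ± 2.95 CPM, though it overlaps an opposite-strand gene. Restricted to genes without such overlap the list had an adjusted p of 2.51e-10. DNA replication genes rose in 22 of 37 cases and fell in 5 (22 and 5 adjusted over the list alone), at an adjusted p of 0.00756 (0.843 with an estimated correlation, 0.00440 to 0.843 over the camera settings). Without control replicate 1 none fell, without control replicate 2 or AURKB replicate 1, 3 fell, and without AURKB replicate 2 or 3, 2 fell. The sliding clamp PCNA rose from 97.2 ± 4.25 to 275 ± 16.9 CPM, and cyclin E2 (CCNE2), which overlaps an opposite-strand gene, by 2.72 ± 0.31 on the log2 scale. Replication histones fell in 7 of 8 cases (8 adjusted over the list alone, adjusted p = 0.00173, and 0.290 with an estimated correlation, 0.00173 to 0.290 over the camera settings), as with HIST2H2BE (-3.44 ± 0.21) and HIST1H2BC (-2.91 ± 0.44).

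Interferon response genes fell in 23 of 32 cases and rose in 2 (23 and 2 adjusted over the list alone), at a camera adjusted p of 0.00173 (0.544 with an estimated correlation, 0.00129 to 0.544 over the camera settings). BST2 fell from 51.3 ± 5.34 to 0.766 ± 0.144 CPM and IFITM1 by 5.32 ± 0.77 on the log2 scale (84.3-fold, interval 23.1 to 699.6 without AURKB replicate 2). In the tetraspanin and vesicle membrane list 6 of 33 tested members rose and 19 fell (7 and 19 adjusted over the list alone), at an adjusted p of 0.00255 (0.290 with an estimated correlation, 9.13e-04 to 0.290 over the camera settings). TSPAN1 fell to 10.3 ± 0.534 CPM and TSPAN15 to 0.6098 ± 0.305 CPM. Lysosome genes fell in 28 of 49 cases and rose in 10 (28 and 10 adjusted over the list alone, adjusted p = 0.0166, and 0.542 with an estimated correlation, 0.0109 to 0.542 over the camera settings). GAA fell by 2.95 ± 0.29 and the cathepsin CTSH by 1.52 ± 0.12 on the log2 scale. Of the epithelial junction genes 5 of 27 tested members rose and 17 fell (5 and 18 adjusted over the list alone), at an adjusted p of 0.0115 (0.602 with an estimated correlation, 0.00986 to 0.602 over the camera settings). The tight junction protein TJP3 fell from 13.2 ± 4.49 to 0.187 ± 0.0307 CPM, and the trafficking GTPase RAB25 was 299.7-fold (95% counting interval 53.4 to 11875) lower, or at least 67.05-fold without AURKB replicate 1, which held its only count. Glycolysis genes fell in 16 of 23 cases and rose in 2 (16 and 2 adjusted over the list alone, adjusted p = 0.00439, and 0.582 with an estimated correlation, 0.00234 to 0.582 over the camera settings), with ENO2 at -2.07 ± 0.25 and SLC16A3 at -1.39 ± 0.07. The interferon, tetraspanin, lysosome, junction and glycolysis lists did not pass among genes with no opposite-strand gene (adjusted p = 0.0763, 0.160, 0.0763, 0.0763 and 0.0501). Their members were fewer there (32 to 19, 33 to 17, 49 to 29, 27 to 15 and 23 to 12), while their medians in the fit of all genes grew in size, from -1.02 to -1.39, -0.51 to -0.78, -0.30 to -0.63, -0.75 to -0.84 and -0.39 to -0.55. That fit set genes with no opposite-strand gene lower as a whole, with 1945 higher and 2649 lower. Scaled and fitted alone, 2232 of them were higher and 2334 lower. The larger medians therefore do not show that the calls were lost through fewer members alone.

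Among genes with no opposite-strand gene, GDA, TLR2 and ONECUT3 rose in AURKB cells. The innate immune receptor TLR2 (ENSG00000137462, chromosome 4, 154622652 to 154626851) rose from 0.111 ± 0.0578 to 30.1 ± 4.29 CPM, and the transcription factor ONECUT3 (ENSG00000205922, chromosome 19, 1752372 to 1780987), from 0.316 ± 0.198 to 59.6 ± 4.998 CPM. PARVB rose to 43.03 ± 1.46 CPM. GDA stood at 14.9 ± 0.313 CPM, 318-fold (95% counting interval 108 to 1544) above control cells, whose 3 counts lay in replicate 1 (at least 214-fold without it). Calretinin, CALB2 (ENSG00000172137, chromosome 16, 71392616 to 71424341), had no count in AURKB cells against 45.8 ± 11.7 CPM in control cells, at least 905-fold lower. TDRD5 was at least 243-fold lower, FIBIN 653-fold (95% counting interval 117 to 25813) lower and the AMPK subunit PRKAA2 308-fold (95% counting interval 84.9 to 2548) lower. The only FIBIN count in AURKB cells came from replicate 3 (at least 145-fold without it). The adhesion receptor LPHN2 fell from 55.02 ± 7.46 to 0.136 ± 0.0791 CPM, and BCAN was 307-fold (95% counting interval 105 to 1493) lower with its 3 counts in AURKB replicate 3 (at least 204-fold without it). Unlike the genes above, LPHN2 and BCAN overlap an opposite-strand gene. CHI3L1, a secreted glycoprotein, fell from 91.02 ± 77.1 to 0.441 ± 0.1601 CPM, a log2 fold change of -7.67 ± 0.92, or -6.70 without control replicate 3. With opposite-strand genes included, PYURF, DEXI and AC119673.1 stood at least 799-fold, 551-fold and 383-fold above control cells with 0 counts. ZNF593, 1693-fold (95% counting interval 303 to 66919.9) (at least 380.4-fold without control replicate 1), and JSRP1 (9.58 ± 0.27, or 2159.6-fold, interval 387 to 85326 without control replicate 3) rose too. All 5 overlap an opposite-strand gene and had 0 to 2 counts over the MYC libraries.

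Other lists moved both ways in AURKB cells. ATF4 and amino acid response genes had 3 risen and 15 fallen members of 25 (4 and 15 adjusted over the list alone, adjusted p = 0.0645). p53 targets had 10 risen and 9 fallen members of 30 (10 and 9 adjusted over the list alone, adjusted p = 0.874, median 0.07, mean -0.06, test upward), and inflammatory cytokines and NF-kB targets 7 risen and 11 fallen members of 23 (7 and 12 adjusted over the list alone, adjusted p = 0.496). Fatty acid synthesis and desaturation had 4 risen and 13 fallen members of 21 (4 and 13 adjusted over the list alone) at an adjusted p of 0.0513 (0.0432 to 0.574 over the camera settings). This list passed without control replicate 1, 2 or 3 or AURKB replicate 1 (adjusted p = 0.0444, 0.0432, 0.0445 and 0.0496), and only 2 members rose without control replicate 2 or 3 or AURKB replicate 1 or 3. With all libraries kept, it also passed under each of the other scalings (camera adjusted p = 0.0441 to 0.0497). FADS2 fell to 43.95 ± 1.95 CPM and the lipogenic regulator SREBF1 from 254 ± 12.3 to 68.1 ± 2.73 CPM. PHGDH, the entry enzyme of serine synthesis, fell from 80.4 ± 6.75 to 32.7 ± 2.11 CPM. Nucleotide synthesis genes had 16 risen and 7 fallen members of 30 (17 and 7 adjusted over the list alone, adjusted p = 0.138) and cholesterol synthesis and uptake genes 8 risen and 12 fallen members of 24 (8 and 12 adjusted over the list alone, adjusted p = 0.623, median -0.11, mean 0.01, test downward). Nuclear-encoded oxidative phosphorylation genes had 15 risen and 9 fallen members of 40 (14 and 9 adjusted over the list alone, adjusted p = 0.316) and ribosome biogenesis genes 14 risen and 10 fallen members of 35 (14 and 10 adjusted over the list alone, adjusted p = 0.596). Without control replicate 2 the phosphorylation genes had 14 risen and 4 fallen members. Single members with large changes were thymidylate synthase (TYMS), FDPS of cholesterol synthesis, and the respiratory chain subunits NDUFA2 and UQCRB, which rose by 1.93 ± 0.10, 4.51 ± 0.27, 2.85 ± 0.32 and 1.74 ± 0.13 on the log2 scale. These 4 overlap an opposite-strand gene. TM7SF2 fell to 3.99 ± 0.4097 CPM, and the ribosome biogenesis genes PUS7 and UTP20 rose to 56.2 ± 2.12 and 91.6 ± 2.35 CPM. In all, 4928 genes rose and 4986 fell, 1832 and 2409 of them 2-fold or more. Among the 7125 genes with no opposite-strand gene, 1945 rose and 2649 fell, with 560 and 1318 at 2-fold or more, and with these genes scaled and fitted alone 2232 rose and 2334 fell (680 and 1187 at 2-fold or more). The authors' deposited table held 5206 higher and 5206 lower genes, and the 9431 called in both had the same sign.

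In HRAS cells epithelial junction and basal genes fell and NRF2 targets rose. Of the epithelial junction genes 0 of 27 tested members rose and 25 fell (0 and 26 adjusted over the list alone), with a median log2 fold change of -3.36, a camera adjusted p of 2.64e-12 and an adjusted p of 0.290 with an estimated correlation, 6.46e-13 to 0.290 over the camera settings. E-cadherin, CDH1 (ENSG00000039068, chromosome 16, 68771128 to 68869445), fell from 137 ± 4.103 to 0.197 ± 0.181 CPM (-9.41 ± 0.25, adjusted p = 6.61e-12), a log2 fold change of -8.80 without HRAS replicate 2 and -10.24 without replicate 3. The tight junction gene MARVELD3 had no count in HRAS cells and was at least 212-fold lower. Basal cytokeratin and basal lamina genes fell in 15 of 16 cases (15 adjusted over the list alone), at an adjusted p of 7.11e-08 (0.290 with an estimated correlation, 1.09e-08 to 0.290 over the camera settings). The hemidesmosome collagen COL17A1 (ENSG00000065618, chromosome 10, 105791044 to 105845760) fell from 710.0 ± 99.2 to 1.63 ± 0.0694 CPM, and the atypical cadherin FAT2 (ENSG00000086570, chromosome 5, 150883654 to 150948505) from 518 ± 65.99 to 0.147 ± 0.0866 CPM (-11.67 ± 0.24). Keratinization genes fell in 8 of 24 cases (8 adjusted over the list alone), with a median of -3.83, or -2.13 with genes at 0 counts set to their bound, at an adjusted p of 0.0200 (0.828 with an estimated correlation, 0.0105 to 0.828 over the camera settings). SPRR1B was 807-fold (95% counting interval 144 to 31911) lower, or at least 174-fold without HRAS replicate 2, which held its only count. This call was lost with limma-voom. Involucrin (IVL) fell from 9.82 ± 1.93 to 0.0525 ± 0.09102 CPM (-7.32 ± 1.29, or at least 153-fold without HRAS replicate 2).

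Mesenchymal genes rose in 18 of 27 cases and fell in 6 (19 and 6 adjusted over the list alone), at an adjusted p of 0.0195 (0.544 with an estimated correlation, 0.0171 to 0.544 over the camera settings). The collagen COL6A2 rose from 0.452 ± 0.166 to 46.9 ± 3.497 CPM, and periostin (POSTN) reached 7.61 ± 0.269 CPM, 163-fold (95% counting interval 55.5 to 793) (329-fold, interval 58.9 to 13038 without control replicate 1). NRF2 targets and pentose phosphate genes rose in 21 of 24 cases and fell in 3 (21 and 3 adjusted over the list alone, adjusted p = 2.75e-05, and 0.544 with an estimated correlation, 1.56e-05 to 0.544 over the camera settings). The aldo-keto reductases AKR1C2, one of a family of close paralogs, and AKR1B10 rose from 64.96 ± 27.4 to 2005 ± 65.4 CPM and from 0.787 ± 0.221 to 12.4 ± 1.66 CPM. In the mitosis list 25 rose and 4 fell of 35 (26 and 4 adjusted over the list alone), at an adjusted p of 9.07e-04 (0.602 with an estimated correlation, 2.51e-04 to 0.602 over the camera settings). Only 1 of them fell without control replicate 1, and 2 without control replicate 2 or HRAS replicate 3. CDK1 rose from 71.4 ± 3.45 to 149 ± 9.54 CPM and BIRC5 to 101.3 ± 5.104 CPM. ER chaperone genes rose in 13 of 20 cases and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 0.00416, and 0.553 with an estimated correlation, 0.00284 to 0.590 over the camera settings), SEL1L by 1.28 ± 0.07 and PDIA6 by 1.39 ± 0.08 on the log2 scale. Glycolysis genes fell in 16 of 23 cases and rose in 5 (16 and 5 adjusted over the list alone, adjusted p = 0.00773, and 0.602 with an estimated correlation, 0.00506 to 0.602 over the camera settings). The glucose transporter SLC2A1 fell from 133 ± 4.41 to 24.5 ± 2.68 CPM and ENO2 to 2.62 ± 0.194 CPM. The mesenchymal, ER chaperone and keratinization lists did not pass among genes with no opposite-strand gene (adjusted p = 0.366, 0.590 and 0.0594). With tested members down from 27 to 14, 20 to 7 and 24 to 18 their medians in the fit of all genes went from 1.41 to 1.13, 0.47 to 0.00 and -3.83 to -3.48 (-2.13 to -1.84 for keratinization with genes at 0 counts set to their bound).

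**Figure D4:**
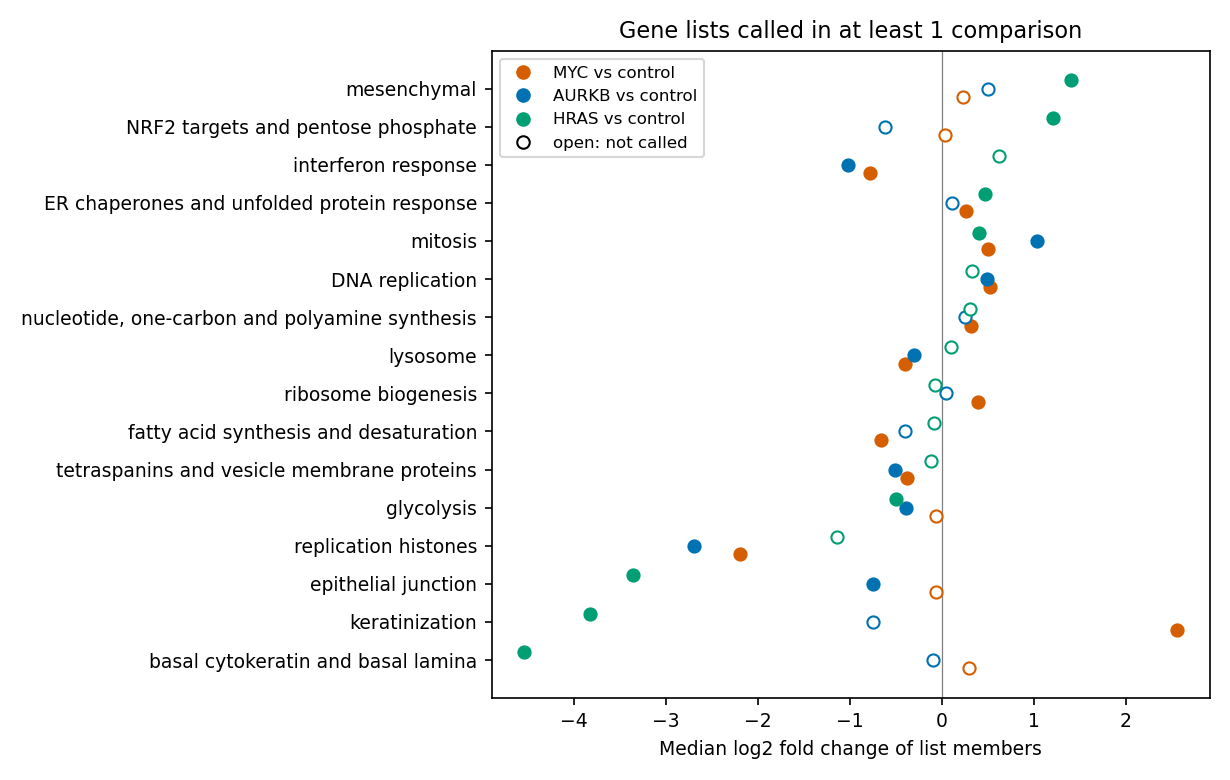
Median log2 fold change against control of the gene lists called by camera in at least 1 of 3 comparisons, filled where the list passed and open where it did not. Epithelial junction and basal lists lie at -3.36 and -4.54 in HRAS cells, and keratinization at 2.56 in MYC and -3.83 in HRAS cells. No list passed with an estimated correlation.

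Among genes with no opposite-strand gene, the lipid droplet protein CIDEC (ENSG00000187288, chromosome 3, 9908398 to 9921938) rose in HRAS cells from 0 counts to 14.97 ± 1.15 CPM, at least 319-fold. The chemokine receptor DARC rose from 0.0644 ± 0.07405 to 58.1 ± 4.47 CPM (9.74 ± 0.33, or 2516-fold, interval 451 to 99416 without control replicate 2). The oestrogen sulfotransferase SULT1E1 reached 31.5 ± 0.5703 CPM, 675-fold (95% counting interval 231 to 3277), or at least 458-fold without control replicate 2. The calcium channel subunit CACNG8 reached 15.1 ± 1.94 CPM, 967-fold (95% counting interval 173 to 38226), and the transcription factor TBX18 10.3 ± 0.435 CPM, 657-fold (95% counting interval 118 to 25978). These 2 rises were at least 209-fold and at least 142-fold without control replicate 3. CALB2 was at least 1105-fold lower. The keratinocyte anchoring protein LAD1 (ENSG00000159166, chromosome 1, 201342372 to 201368736) was 5762-fold (95% counting interval 1595 to 47584) lower than its 161 ± 19.3 CPM in control cells. DENND1C, which unlike the genes above overlaps an opposite-strand gene, and C1orf210 had no count in HRAS cells. They were at least 423-fold and 244-fold lower. The receptor PTAFR fell from 109.7 ± 5.798 to 0.0946 ± 0.125 CPM (-10.05 ± 0.31, 5102-fold, interval 915 to 201546 without HRAS replicate 2 and -9.46 without replicate 3). PYURF, DEXI, AC119673.1 and MSMP, which overlap an opposite-strand gene, stood at least 1158-fold, 560.0-fold, 454-fold and 406-fold above control cells with 0 counts.

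Lists that did not pass in HRAS cells still held large single changes. Lysosome genes, lower in MYC and AURKB cells, had 18 risen and 14 fallen members of 49 (18 and 14 adjusted over the list alone, adjusted p = 0.424, median 0.10), or 15 and 8 without HRAS replicate 3, and a median of -0.09 among genes with no opposite-strand gene. Interferon response genes had 18 risen and 4 fallen members of 32 (18 and 4 adjusted over the list alone, adjusted p = 0.0563, 0.0474 to 0.611 over the camera settings), with a median of 0.62, or 0.30 among genes with no opposite-strand gene. This list passed without control replicate 3 (adjusted p = 0.0474). ERK pathway output genes had 13 risen and 10 fallen members of 28 (13 and 11 adjusted over the list alone, adjusted p = 0.770). In that list IL1RL1, the receptor of interleukin 33, rose from 9.14 ± 3.74 to 1289 ± 281 CPM and the feedback inhibitor SPRY4 from 50.2 ± 7.63 to 236 ± 13.2 CPM. Fatty acid synthesis and desaturation had 7 risen and 8 fallen members of 21 (7 and 8 adjusted over the list alone, adjusted p = 0.951), with a median of -0.09 and a mean of 0.20. The acyl-CoA synthetases ACSL5 and ACSL1 rose from 1.79 ± 0.541 to 43.4 ± 4.52 CPM and from 187 ± 35.6 to 742 ± 64.002 CPM. Of 18 luminal genes 8 were tested. They had 4 risen and 3 fallen members of 8 (4 and 3 adjusted over the list alone, adjusted p = 0.878, median 0.07, mean -0.68, test downward), with 2 risen and 4 fallen without control replicate 1, HRAS replicate 1 or HRAS replicate 3, and 3 and 5 without control replicate 2. Nucleotide synthesis genes had 15 risen and 8 fallen members of 30 (15 and 8 adjusted over the list alone, adjusted p = 0.187) and cholesterol synthesis and uptake genes 8 risen and 10 fallen members of 24 (8 and 10 adjusted over the list alone, adjusted p = 0.850, median -0.14, mean 0.12, test downward). Nuclear-encoded oxidative phosphorylation genes had 13 risen and 12 fallen members of 40 (13 and 12 adjusted over the list alone, adjusted p = 0.998, median -0.04, mean 0.04, test upward) and ribosome biogenesis genes 13 risen and 12 fallen members of 35 (13 and 12 adjusted over the list alone, adjusted p = 0.878). The mitochondrial folate enzyme MTHFD2 rose from 116 ± 3.54 to 284 ± 8.44 CPM, while the ribosome factor BOP1 fell from 44.2 ± 8.27 to 15.02 ± 1.49 CPM and the sterol demethylase CYP51A1 from 21.1 ± 6.33 to 4.701 ± 0.316 CPM. UTP20 rose to 91.5 ± 2.16 CPM. TYMS, FDPS, NDUFA2 and UQCRB, which overlap opposite-strand genes, rose by 2.10 ± 0.10, 5.10 ± 0.28, 3.03 ± 0.32 and 1.60 ± 0.13 on the log2 scale. In all, 5224 genes rose and 5097 fell, 2194 and 2613 of them 2-fold or more. Among the 7125 genes with no opposite-strand gene, 2117 rose and 2721 fell, with 735 and 1468 at 2-fold or more. With these genes scaled and fitted alone 2415 rose and 2464 fell, 812 and 1338 of them 2-fold or more. The authors' deposited table held 5473 higher and 5478 lower genes, and the 9813 called in both had the same sign.

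Some genes of extracellular vesicle release moved in opposite directions in MYC and HRAS cells. RAB27A and RAB27B, GTPases that dock multivesicular bodies at the plasma membrane, fell in MYC cells by 0.29 ± 0.09 and 1.04 ± 0.06 on the log2 scale and rose in HRAS cells by 0.73 ± 0.08 and 0.52 ± 0.06. The fall of RAB27A in MYC cells did not pass when only these 2 groups were fitted. In AURKB cells RAB27B fell by 0.57 ± 0.06 and RAB27A had a log2 fold change of 0.01 ± 0.09 (adjusted p = 0.909). CD63, a tetraspanin of late endosomes, fell from 278 ± 28.5 to 213 ± 13.1 CPM in MYC cells and rose to 420.2 ± 7.96 CPM in HRAS cells, with -0.05 ± 0.08 in AURKB cells (adjusted p = 0.581). CD9 fell in all 3 lines, by 0.57 ± 0.11, 0.58 ± 0.11 and 1.88 ± 0.12 in MYC, AURKB and HRAS cells. CD81 fell in AURKB cells by 0.51 ± 0.09, passed at an adjusted p of 0.0407 in MYC cells (-0.24 ± 0.09) and did not pass in HRAS cells (-0.12 ± 0.09). The MYC call of CD81 was lost without control replicate 2, control replicate 3, MYC replicate 1 or MYC replicate 2 (-0.24, -0.14, -0.22 and -0.23), with replicate number as a block, and with only these 2 groups fitted. CD82 fell from 111 ± 7.26 to 2.86 ± 0.548 CPM in HRAS cells. TFEB, a regulator of lysosome genes, fell from 20.04 ± 1.87 CPM to 10.8 ± 3.33, 7.71 ± 0.935 and 7.51 ± 0.737 CPM. The neutral sphingomyelinase SMPD2 fell in HRAS cells by 0.26 ± 0.09 (adjusted p = 0.0226), a call lost without control replicate 1, HRAS replicate 1 or HRAS replicate 2 (-0.22, -0.25 and -0.27), with upper-quartile scaling or with no filter. SMPD3 was not among the tested genes. LAMP1 did not pass in any line (0.06 ± 0.08, -0.16 ± 0.08 and -0.09 ± 0.08).

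Syntenin (SDCBP), an adaptor of vesicle formation with the ESCRT complexes, fell from 201 ± 23.2 to 123 ± 15.998 CPM in MYC cells and rose to 406 ± 13.8 and 538 ± 26.5 CPM in AURKB and HRAS cells. Of the ESCRT genes 5 rose and 4 fell of 32 (5 and 4 adjusted over the list alone) in MYC cells, or 4 and 8 without MYC replicate 1. In AURKB cells 11 rose and 8 fell of 32 (11 and 8 adjusted over the list alone) and in HRAS cells 10 rose and 12 fell of 32 (10 and 12 adjusted over the list alone). The list passed in none of them (adjusted p = 0.945, 0.569 and 0.818). In MYC cells the ESCRT median was -0.01 against a mean of 0.02 and an upward test, and in HRAS cells 0.05 against -0.03 and a downward test. MVB12B rose from 7.25 ± 2.27 to 15.7 ± 1.18 CPM in MYC cells. CHMP4C and SNF8 rose to 30.2 ± 2.86 and 43.7 ± 3.55 CPM in AURKB cells and SNF8 to 50.4 ± 1.09 CPM in HRAS cells, both genes with opposite-strand overlap. Vesicle docking and secretion genes had 10 risen and 10 fallen members of 35 (10 and 11 adjusted over the list alone) in MYC cells. They had 11 risen and 13 fallen members of 35 (11 and 13 adjusted over the list alone) in AURKB cells (adjusted p = 0.777 and 0.855), with both tests pointing down while the means were 0.04 and 0.00. In HRAS cells they had 9 risen and 20 fallen members of 35 (9 and 20 adjusted over the list alone, adjusted p = 0.0513, 0.0402 to 0.290 over the camera settings). This list passed without control replicate 1, control replicate 2 or HRAS replicate 3 (adjusted p = 0.0402, 0.0402 and 0.0479). With all libraries kept, it also passed when scaled by library size only (camera adjusted p = 0.0486). The secretion factor UNC13D rose from 2.34 ± 0.564 to 17.2 ± 2.1998 CPM in MYC and to 14.7 ± 1.003 CPM in AURKB cells. RAB31 rose to 31.9 ± 6.73, 34.2 ± 1.95 and 96.2 ± 9.02 CPM from 11.7 ± 1.59 CPM, and the RAB27 effector EXPH5 fell from 15.9 ± 2.33 to 1.58 ± 0.106 CPM in HRAS cells. Ceramide and sphingolipid genes had 3 risen and 15 fallen members of 34 (3 and 15 adjusted over the list alone) in MYC cells (adjusted p = 0.0513, or 0.00953 without MYC replicate 1 and 0.00953 to 0.602 over the camera settings). With all libraries kept, these genes also passed in MYC cells under each of the other scalings (camera adjusted p = 0.0267 to 0.0497). In AURKB cells they had 11 risen and 11 fallen members of 34 (11 and 11 adjusted over the list alone, adjusted p = 0.868) and in HRAS cells 16 risen and 10 fallen members of 34 (16 and 10 adjusted over the list alone, adjusted p = 0.407, median 0.27, mean -0.15, test upward). SPTLC3 of serine palmitoyltransferase fell by 1.18 ± 0.26 in MYC cells, SPHK1 by 2.45 ± 0.12 in AURKB cells and the ceramidase ACER2 by 2.24 ± 0.20 in HRAS cells. Autophagy genes had 5 risen and 7 fallen members of 30 (5 and 7 adjusted over the list alone) in MYC cells (adjusted p = 0.778), and in AURKB cells their test pointed up while their mean log2 fold change was -0.02 (adjusted p = 0.428). They had 12 risen and 8 fallen members of 30 (12 and 8 adjusted over the list alone) in AURKB and 12 risen and 7 fallen members of 30 (12 and 6 adjusted over the list alone) in HRAS cells (adjusted p = 0.415 in the latter). Tetraspanin and vesicle membrane genes had 7 risen and 14 fallen members of 33 (7 and 14 adjusted over the list alone) in HRAS cells (adjusted p = 0.209). Between oncogene lines the ESCRT and tetraspanin lists did not pass, and the docking list passed only in AURKB against HRAS cells, with 20 higher and 8 lower of 35 (20 and 8 adjusted over the list alone, adjusted p = 0.0456, and 0.277 with an estimated correlation). In HRAS cells HEXA, which overlaps an opposite-strand gene, rose to 21.7 ± 1.02 CPM and CTSH fell to 12.2 ± 1.54 CPM.

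Markers of other cell types and of RNA quality were tested the same way. Of 11 fibroblast genes 6 were tested, with 3 risen and 2 fallen members of 6 (3 and 2 adjusted over the list alone) in HRAS cells (adjusted p = 0.659). Of endothelial genes 2 rose and 0 fell of 3 (2 and 0 adjusted over the list alone) in AURKB cells (adjusted p = 0.104), and of 12 immune genes only 2 had enough counts, too few for a list test. Mitochondrially encoded mRNAs held 1.29% to 3.03% of counts per library. They had 1 risen and 9 fallen members of 13 (1 and 9 adjusted over the list alone) in HRAS cells (adjusted p = 0.187), where 5 fell without control replicate 1 or HRAS replicate 1. In MYC cells they had 3 risen and 0 fallen members of 13 (1 and 0 adjusted over the list alone, adjusted p = 0.176). There 7 rose without control replicate 1 and 8 without MYC replicate 1, and the list passed (adjusted p = 0.0146 and 0.0291, 0.0146 to 0.886 over the camera settings). Without any other of these libraries, control replicate 2 or 3 or MYC replicate 2 or 3, 1 rose. Replication histones had 0 risen and 7 fallen members of 8 (0 and 7 adjusted over the list alone) in HRAS cells (adjusted p = 0.0772).

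Set against each other, MYC and HRAS cells differed in epithelial genes. LAD1 was 10426-fold (95% counting interval 2886 to 86098) higher in MYC cells, and A2ML1 and the cornified envelope protein SCEL, with no count in HRAS cells, were at least 972-fold and 829-fold higher. A2ML1 and SCEL overlap an opposite-strand gene. Without an opposite-strand gene, SPRR1B was 5289.7-fold (95% counting interval 949 to 208976) and SPRR1A at least 498-fold higher. These 4 keratinocyte genes moved with MYC replicate 1, without which the difference was at least 422-fold for A2ML1, at least 411-fold for SCEL and at least 109-fold for SPRR1A. For SPRR1B it was 1783-fold, interval 319 to 70485, and at least 1140.2-fold without HRAS replicate 2. The adhesion molecule CADM3, haptoglobin (HP) and the fatty acid carrier FABP4 had no count in MYC cells and 685 ± 29.7, 186 ± 35.1 and 70.1 ± 2.67 CPM in HRAS cells, at least 14786-fold, 4046-fold and 1516-fold apart. CADM3, HP and FABP4 overlap an opposite-strand gene, and MYC and HRAS cells lie on opposite sides of the opposite-strand split. For HP and FABP4 the difference between AURKB and HRAS cells, which lie on the same side, is given below. DARC, the potassium channel KCNQ3 and CACNG8 were at least 1250.4-fold, 665-fold and 326-fold lower in MYC cells. List tests between oncogene lines were added after the data were seen, and of 30 lists 7 passed here, 8 between MYC and AURKB cells and 12 between AURKB and HRAS cells. Epithelial junction genes were higher in MYC cells in 25 of 27 cases and lower in 0 (26 and 0 adjusted over the list alone, adjusted p = 4.54e-11, and 0.250 with an estimated correlation). NRF2 targets were lower in 20 of 24 and higher in 3 (20 and 3 adjusted over the list alone, adjusted p = 1.43e-04, and 0.666 with an estimated correlation). In all, 5302 genes were higher in MYC and 5372 in HRAS cells, 2806 and 2631 of them 2-fold or more. Of genes with no opposite-strand gene 2833 were higher in MYC and 2129 in HRAS cells, 1577 and 908 of them 2-fold or more, or 2580 and 2422 (1442 and 1043) when scaled and fitted alone.

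Between MYC and AURKB cells, mitosis genes were lower in MYC cells in 27 of 35 cases and higher in 3 (28 and 3 adjusted over the list alone), with an adjusted p of 9.51e-06 (0.583 with an estimated correlation). Ribosome biogenesis genes were higher in MYC cells in 19 of 35 and lower in 3 (19 and 3 adjusted over the list alone, adjusted p = 0.00680, and 0.817 with an estimated correlation). BGN, which overlaps an opposite-strand gene, had no count in AURKB cells and was at least 714-fold higher in MYC cells. The log2 difference of KRT4 was 7.06 ± 1.34, of S100A7 6.64 ± 1.12 and of SPRR1A 6.13 ± 1.20, and these were 4.94, 4.59 and 3.99 without MYC replicate 1 (196-fold, interval 67.03 to 954 for S100A7 without AURKB replicate 2). With limma-voom BGN, KRT4 and SPRR1A did not pass in this comparison. PYURF and AC119673.1 were at least 808-fold and 388-fold higher in AURKB cells and JSRP1 1685-fold (95% counting interval 466 to 13922), all with an opposite-strand gene. Without one, ONECUT3 (-8.54 ± 0.41, or 2554-fold, interval 458 to 100921 without MYC replicate 2), AURKB (-5.64 ± 0.10) and complement C5 (-2.83 ± 0.19) were lower in MYC than in AURKB cells. In all, 4425 genes were higher and 4300 lower in MYC than in AURKB cells, 1649 and 1378 of them 2-fold or more. Among genes with no opposite-strand gene 2475 were higher and 1525 lower, with 959 and 302 at 2-fold or more. With these genes scaled and fitted alone the split was 2072 and 1936, with 805 and 380 at 2-fold or more.

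AURKB and HRAS cells lie on the same side of the opposite-strand split. Basal genes were higher in AURKB cells in all 16 cases (16 adjusted over the list alone), at an adjusted p of 4.54e-11 (0.250 with an estimated correlation). Epithelial junction genes were higher in 23 of 27 with 1 lower (23 and 1 adjusted over the list alone, adjusted p = 4.54e-11, and 0.250 with an estimated correlation). NRF2 targets were lower in 22 of 24 with 0 higher (22 and 0 adjusted over the list alone, adjusted p = 2.43e-10, and 0.369 with an estimated correlation). Interferon response genes were lower in AURKB cells in 25 of 32 with 1 higher (26 and 1 adjusted over the list alone, adjusted p = 5.80e-07, and 0.250 with an estimated correlation). Mitosis genes were higher in 32 of 35 with 0 lower (32 and 0 adjusted over the list alone, adjusted p = 1.01e-08, and 0.425 with an estimated correlation). Beside these, mitochondrially encoded mRNAs were higher in 9 of 13 with 0 lower (10 and 0 adjusted over the list alone, adjusted p = 0.0103, and 0.817 with an estimated correlation). Replication histones were lower in AURKB cells in 6 of 8 with 0 higher (6 and 0 adjusted over the list alone, adjusted p = 0.0234, and 0.445 with an estimated correlation), so both marks of RNA quality differed between these lines. LAD1 was 5346-fold (95% counting interval 1479 to 44150.3) higher in AURKB cells, SCEL at least 377-fold, and ONECUT3 1427-fold (95% counting interval 488 to 6924), or 2768-fold, interval 497 to 109379 without HRAS replicate 2. HP was 3668-fold (95% counting interval 1255 to 17790.2) higher in HRAS cells (7317-fold, interval 1313 to 289014 without AURKB replicate 3), lipoprotein lipase (LPL) at least 217-fold, and FABP4 1374-fold (95% counting interval 470.0 to 6666) (2767-fold, interval 496 to 109296 without AURKB replicate 1). IL1RL1 (-9.88 ± 0.36) and the contactin CNTN3, 950.2-fold (95% counting interval 170.2 to 37562) higher in HRAS cells (at least 213-fold without AURKB replicate 1), followed. In all, 4314 genes were higher and 4064 lower in AURKB than in HRAS cells, 1519 and 1740 of them 2-fold or more, and 2131 and 1966 among genes with no opposite-strand gene (2148 and 1954 when scaled and fitted alone). At 2-fold or more these were 806 and 851, or 812 and 849.

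A common set of genes changed in all 3 lines. DKK1, an inhibitor of WNT signalling, rose from 8.08 ± 4.36 CPM to 54.5 ± 3.796 and 61.1 ± 5.25 CPM in AURKB and HRAS cells and by 2.61 ± 0.56 on the log2 scale in MYC cells, or 1.44 without MYC replicate 1. The cytokine CSF3 rose from 41.1 ± 10.7 to 289 ± 28.2, 232 ± 6.55 and 256 ± 90.99 CPM in MYC, AURKB and HRAS cells. The apoptosis inhibitor BIRC3 rose from 14.3 ± 4.45 to 71.5 ± 9.33, 178 ± 12.8 and 148 ± 70.3 CPM. GFPT2, of hexosamine synthesis, rose from 17.3 ± 8.39 to 146.8 ± 66.5, 80.6 ± 7.95 and 135 ± 7.77 CPM. NAV3 rose from 2.63 ± 1.94 to 20.8 ± 3.61, 11.7 ± 0.989 and 17.3 ± 2.25 CPM and STRIP2 from 5.63 ± 2.54 to 23.7 ± 0.208, 27.4 ± 1.14 and 40.3 ± 0.7702 CPM. CAPN6 fell from 10.2 ± 4.34 to 0.0759 ± 0.021001, 0.1696 ± 0.0573 and 0.0973 ± 0.0591 CPM. SPTSSB, a subunit of serine palmitoyltransferase, fell by 4.33 ± 0.46 (-4.94 without MYC replicate 1), 6.09 ± 0.56 and 7.07 ± 0.60, and CALB2 in MYC cells by 5.44 ± 0.39 (-6.29 without MYC replicate 1). The adaptor LAT2 fell from 25.004 ± 5.79 to 1.27 ± 0.383, 0.119 ± 0.117 and 0.565 ± 0.186 CPM (log2 fold change -7.65 ± 0.40 in AURKB cells, or 492-fold, interval 136 to 4069 without AURKB replicate 3). The fatty acid transporter SLC27A6 fell from 10.1 ± 0.795 to 0.3896 ± 0.124, 0.153 ± 0.0509 and 0.568 ± 0.182 CPM, and FAM131B from 10.4 ± 1.6997 to 0.815 ± 0.559, 0.493 ± 0.212 and 0.2104 ± 0.0453 CPM. SPRY2 of the ERK output list rose from 10.5 ± 1.95 to 30.2 ± 4.68, 32.6 ± 1.56 and 40.2 ± 2.32 CPM. That list had 14 risen and 9 fallen members of 28 (14 and 9 adjusted over the list alone) in MYC and 4 risen and 15 fallen members of 28 (4 and 15 adjusted over the list alone) in AURKB cells (adjusted p = 0.275 and 0.240). SPRY1 rose to 7.55 ± 0.879 CPM in MYC cells and IL1RL1 fell to 1.53 ± 0.782 and 1.36 ± 0.386 CPM in MYC and AURKB cells. In total 1244 genes rose and 1407 fell in all 3 lines.

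Calls of MYC and AURKB cells overlapped in 4552 genes of the same direction and 821 of opposite direction, where independent lists would share 2379 and 2379.7. For AURKB and HRAS cells these numbers were 6560 and 1026 against 3409.6 and 3410.1, and for MYC and HRAS cells 3035 and 2154 against 2478 and 2476. Among genes with no opposite-strand gene the same-direction overlaps were 2232, 2981 and 1522 and the opposite ones 393, 503 and 1048. Simulated unchanged lines, set against control libraries simulated from the control means, shared 0 calls in 20 simulations. Few genes are called in unchanged data and genes were drawn independently, so these simulations could not show a deviating control line. The covariance of log2 fold changes across genes was 0.920 for MYC and AURKB, 2.31 for AURKB and HRAS and 0.195 for MYC and HRAS cells, against simulated values of 0.0682, 0.0677 and 0.0676. The correlations across genes, which are not independent replicates, were 0.481, 0.653 and 0.0904, against 0.494, 0.499 and 0.512 in the simulations. The simulated correlations arise from noise in the control libraries that both comparisons share. They are therefore no baseline for the measured correlations. Among genes with no opposite-strand gene the measured correlations were 0.627, 0.472 and 0.127, so the order of the first pair and the second turned, and the correlation of AURKB and HRAS cells fell from 0.653 to 0.472. No simulation was made for these genes alone. With 3 control libraries the controls could not be split into 2 sets of at least 2, so part of the excess may come from the shared controls.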

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

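Of 457 numbers under the alternatives (genes called, gene lists called and genes shared between lines), 417 stayed within a set ratio of the main number and 40 moved beyond it. Staying within the ratio does not mean an equal number. For example, 10 lists called in AURKB cells with replicate number as a block, against 8 in the main test, counted as within it. All 45 tests of the introduced oncogenes in their own cells held. Of 1167 list tests 1070 held, 59 became stronger and 38 weaker, and of 3560 tests of named genes 3533 held, 8 became stronger and 19 weaker. No test that passed in either setting turned its direction.

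With a minimum fold in the test (glmTreat), the genes higher and lower were 303 and 549 in MYC, 1111 and 1516 in AURKB, and 1438 and 1829 in HRAS against control cells. They were 2068 and 1920 for MYC against HRAS, 806 and 757 for MYC against AURKB, and 972 and 1089 for AURKB against HRAS cells.

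With the stricter filter, genes at least 2-fold higher and lower were 326 and 612 in MYC, 702 and 1192 in AURKB, and 932 and 1395 in HRAS against control cells. They were 1538 and 1205 for MYC against HRAS, 776 and 433 for MYC against AURKB, and 784 and 849 for AURKB against HRAS cells.

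With the estimated correlation 0 gene lists were called in MYC, 0 in AURKB and 0 in HRAS cells, against 11, 8 and 8 at the set correlation. With fry, which tests a list against no change and not against other genes, the numbers were 20, 18 and 21. Among genes with no opposite-strand gene 3 lists were called in AURKB and 5 in HRAS cells. The called lists had fewer members there, and for the 5 lists no longer called in AURKB cells the median of these members, taken from the fit of all genes, was larger in size than that of all members. In that fit, genes with no opposite-strand gene lay lower than when scaled alone, so these medians do not show why the calls were lost.

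With 2-fold calls, MYC and AURKB cells shared 1397 genes of the same and 77 of opposite direction, MYC and HRAS cells 752 and 419, and AURKB and HRAS cells 2425 and 266. In all 3 lines 184 genes were higher and 443 lower.

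With the replicate number as a replicate block, 3600 genes were higher and 3498 lower in MYC, 4891 and 4970 in AURKB, and 5224 and 5078 in HRAS against control cells. In these comparisons 12, 10 and 10 gene lists were then called. Lists gained were ceramide in MYC, fatty acid and ATF4 in AURKB, and vesicle docking and interferon in HRAS cells (camera adjusted p = 0.0452, 0.0452, 0.0472, 0.0476 and 0.0476). Libraries of the same number correlated at -0.0390 to 0.0959 over 18 pairs. Of 12 libraries, 7 correlated best with a library of their own number among the other groups. The correlations were low, so they give little sign of pairing by number, but they do not settle it. Upper-quartile scaling shifted the median log2 difference of MYC against HRAS cells by -0.104.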

Other observations

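The PPARG list was chosen after FABP4, LPL and CIDEC were seen high in HRAS cells. PPARG, the regulator of fat cell genes, was at 63.5 CPM in HRAS and 12.1 CPM in AURKB cells. The fatty acid receptor CD36 stood at 27.6 against 0.102 CPM, and the droplet proteins PLIN4 and PLIN1 at 41.8 against 1.28 CPM and 2.49 against 0.0686 CPM. Of the 14 tested list members, which leave out FABP4, LPL and CIDEC, 10 were higher and 2 lower, with a median log2 difference of 0.743, and LIPE and CPT1A had log2 differences of -1.51 and -0.89. PPARG activity could underlie the lipid genes of HRAS cells, yet the camera p of 0.00345 became 0.0721 with an estimated correlation, and against control cells the median was 0.225 (p = 0.367).

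The tests of opposite-strand reads and of a shared response were chosen after the result was seen. Of 385 genes 4-fold or more higher in both AURKB and HRAS cells than in both control and MYC cells, 97.9% overlap an opposite-strand gene, against 52.5% of all tested genes. Only 0.112% of genes with no such overlap meet the condition, among them DCN and ALOX5AP, which argues against a shared response as the main source of these rises. Of 226 genes 4-fold or more lower in both lines 107 have no opposite-strand gene and 119 have one, so a shared fall stays open. For the 385 higher genes the median log2 difference was 3.43. It was 3.54 after removal of the trend on GC content and length over all tested genes, in the 90.1% with both values. This argues against a trend shared by genes of like GC content and length as the source. Reads over opposite-strand genes may have been counted differently in the 2 sets of libraries, but no group spans both sets and the strand setting is not stated.

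For MYC replicate 1, the tests of a mixture and of a wrong label were chosen after the result was seen. Thinned to the depth of MYC replicate 3 it still had 1659 genes 2-fold apart, against 1618 before, so depth is an unlikely source. Of the 245 genes 2-fold higher in it at 5 CPM or more, 74.3% exceeded every other group mean, which argues against a mixture with cells of another group. Its distance to the nearest other group was 1.61 times that to MYC replicates 2 and 3, which argues against a wrong label. Its keratinization genes could reflect a denser culture, which the labels do not record.

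For genes changed in all 3 lines, the tests of chance through shared controls and of genes scaled and fitted alone were chosen after the result was seen. Of 10 simulations of unchanged lines and unchanged controls the highest number was 0. Few genes are called in unchanged data and genes were drawn independently, so this number could hardly be higher and decides little. Without any 1 control library the lowest number was 2182, and at least 2079 of the 2651 genes were called the same way again. Of these genes 50.4% overlap an opposite-strand gene, against 52.5% of all tested genes, but the counting difference would raise this share among rises and lower it among falls, and it was 54.0% of the rises and 47.2% of the falls, so part of the set may come from it. Genes with no such overlap, scaled and fitted alone, gave 1342 genes changed the same way in all 3 lines, against 1315 in the fit of all genes, which argues against the counting difference as the whole source. A change in the only control line itself could give the same pattern and stays open.

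When the 6 libraries of each comparison were split in all 10 ways, 1 of the 10 splits, the real one, called as many genes, at 7202 for MYC, 9914 for AURKB and 10321 for HRAS against control cells. The real numbers were 10674 for MYC against HRAS, 8725 for MYC against AURKB and 8378 for AURKB against HRAS cells. The highest other split called 7 genes for MYC against control and 0 for the other 5, and 10 splits are too few for a share under 0.05.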
